A study of Cereibacter sphaeroides with 12 samples.

How the data were processed

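Expression arrays of 12 samples were analysed, from 5 strains of Cereibacter sphaeroides grown aerobically in a minimal medium. Per the labels' protocols the cultures of 500 ml were bubbled with 30% oxygen, 69% nitrogen and 1% carbon dioxide and taken in exponential growth, RNA was extracted with hot acid phenol, and fragmented cDNA was labelled with biotin. The protocol text of the WT samples also covers photosynthetic growth, and the sample titles, which say aerobic, were followed. The description of the ΔakgR strain with its plasmid names the other regulator, and its title and source name were followed. Groups and replicate numbers came from the titles: WT and ΔcceR with 3 arrays each, ΔakgR with 2, and each deletion strain with its gene on an inducible plasmid with 2. No group with an empty plasmid and no batch or scan date was used here.

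The authors deposited log2 values made with RMA, per the submitters' processing notes, which name RMA and limma without versions. RMA subtracts a background from perfect-match probes, normalizes the arrays by quantiles and summarises the probes of a set. The deposited log2 table held 4490 probe sets with no missing value, and array medians lay between 8.01 and 8.06. Quantile steps force the probes of the arrays to a common distribution, so a shift of most transcripts in 1 direction would be partly removed. The deposited probe set values, which are summarised after that step, still differed in spread, with array SDs of 1.31 to 1.40. A gene whose signal lies near the array's background has its fold change understated.

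Gene names came from the platform annotation given with the table. It gave 1 symbol to 539 probe sets, several to 0 and none to 3951, which stand for 514 genes. Of the 539 symbols 538 were also in the RefSeq gene table of the strain's assembly ASM332471v1, and 0 Entrez numbers matched, so the platform's symbols were kept. RefSeq start positions, matched by symbol, served only to compare probe set numbers with gene order, and none is printed. Probe sets for RSP_1663 and RSP_0981 were not named there, and the check of the deleted genes fixed before the data were examined was not made. Control probe sets, which were to be left out, were not told apart by the numeric IDs of the table and stayed among the probe sets tested. A total of 10 genes had more than 1 probe set, and their brightest probe set stood for them in the list tests. Of the symbols 16 were carried by more than 1 gene, and these are described as the brighter and the dimmer gene or each is given, while atpA, atpD, sdhA, fumC and repA without such a word mean the brighter gene.

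Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited values, with lmFit and eBayes over all 12 arrays, 5 strain means and 7 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over the 4490 probe sets and a threshold of 0.05. Standard errors are those of the moderated fit. The lists of genes were tested with camera at a preset correlation of 0.01 against the other named genes, adjusted over the 14 lists with at least 3 measured members, and repeated with an estimated correlation. A total of 16 lists was fixed before the data were examined. The list for dicarboxylate uptake had 0 named members, and that for the Calvin cycle was too small to test. Where the median, the mean and the camera direction of a list disagree, camera sets the list against the other named genes and not against 0.

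The genes named in the text followed a rule fixed before the data were examined. In each deletion against WT and plasmid against deletion these were the 8 risen and 8 fallen named probe sets with the largest change past the threshold and no overlap between arrays of the strains. From each list up to 4 members past the threshold were taken, or the 2 with the largest change if none passed. In the other comparisons 3 risen and 3 fallen were taken, and 6 genes for each overlap of comparisons. Overlaps were set against the overlap of independent lists, and the correlation and covariance of fold changes against 100 simulations of unchanged strains that share the same arrays. The planned comparison with simulated overlap counts is not used, because unchanged strains gave on average 0.04 to 0.15 calls per comparison and so no overlap to compare.

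The fit was tested on simulated data with 200 of 4490 probe sets changed. Changes of 0.5 on the log2 scale were found in 96% of cases for ΔcceR against WT, 95% for ΔakgR against WT, 84% for return of cceR and 90% for return of akgR, with 7 to 14 false calls over the comparisons. In simulations without an effect camera called 2 of 700 list tests. Genes were simulated there as independent of each other, so this count does not show how often lists of correlated genes are falsely called. The number of arrays, 2 or 3 per strain, limits the precision, and the median standard error of a fold change was 0.06 to 0.08 on the log2 scale.

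Alternatives fixed beforehand were a fit of the compared strains alone, an intensity trend, robust eBayes, array weights, quantile normalization, median centring, a filter on the dimmest 25% of probe sets, an absolute log2 fold change of at least 1, an adjusted p under 0.01, the replicate number as a block and leaving out each array. The settings without the 80 probe sets of the highest numbers, with all probe sets as the background of the list tests, and with no array in common between the comparisons of an overlap were chosen after seeing the data. In the last, the arrays of the shared strain were divided in every way, each part had its own mean in the fit, and the spread of each probe set was still estimated once for both comparisons. Figures were drawn with matplotlib 3.10.9.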

Results

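Messenger RNA levels were measured on Affymetrix expression arrays in 5 strains of Cereibacter sphaeroides (also known as Rhodobacter sphaeroides), a purple bacterium that respires in air and makes a photosynthetic apparatus when oxygen is scarce. All cultures were labelled as grown with oxygen. The strains were the wild type (WT, 3 arrays), a strain lacking RSP_1663, the gene of the regulator CceR (ΔcceR, 3 arrays), a strain lacking RSP_0981, the gene of the regulator AkgR (ΔakgR, 2 arrays), and each deletion strain with its own gene returned on an inducible plasmid (2 arrays each). Each array gave a log2 signal for 4490 probe sets, of which 539 carried a gene symbol, for 514 genes. Arrays of 1 strain correlated with each other at 0.991 to 0.997 across probe sets, which are not independent replicates, and the number of arrays limits the precision of every value. The labels do not say that arrays of a strain came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Neither RSP_1663 nor RSP_0981 had a named probe set in the annotation used here, so the strain labels were not checked through the deleted genes.

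The first comparison asked which transcripts depend on CceR. In ΔcceR the genes of the Entner-Doudoroff pathway, which breaks glucose 6-phosphate down to pyruvate, were higher than in WT, with zwf (glucose 6-phosphate dehydrogenase) up by 2.22 ± 0.08 on the log2 scale (SE, n = 3 and 3 arrays), a fold of 4.66. The genes edd (phosphogluconate dehydratase) and pgl (6-phosphogluconolactonase) were higher by 2.15 ± 0.07 and 2.03 ± 0.08. Of the 2 genes named eda, the aldolase that ends the pathway, 1 rose by 1.08 ± 0.10 and the other changed by -0.20. In all, 4 of the 5 measured members rose and 1 fell, and the same counts held when adjusted over the list alone. The list stood above the other named genes (camera, adjusted p = 1.45e-05), with adjusted p = 0.147 with an estimated correlation. The neighbouring step of pgi, glucose 6-phosphate isomerase, rose by 1.27 ± 0.05, while the lower glycolytic genes eno (enolase) and gpmI (phosphoglycerate mutase) fell by 0.48 ± 0.11 and 0.28 ± 0.05.

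Genes of the photosynthetic apparatus were the other group that rose in ΔcceR, although the cultures had oxygen. The largest increases were in pufL and pufM, the reaction centre subunits, at 2.78 ± 0.07 and 2.78 ± 0.06, a fold of 6.89 and 6.87 (limma, adjusted p = 2.17e-10 and 7.82e-11). They were followed by pufX at 2.29 ± 0.10 and puhA, the third reaction centre subunit, at 2.24 ± 0.06. All 5 probe sets of pufA, which encodes a light-harvesting polypeptide, were higher, by 1.92 to 2.16. Of 27 measured members of the list 17 rose, 0 fell and 10 did not pass the test, and 18 rose when adjusted over the list alone. The list was called up (camera, adjusted p = 3.99e-15), also with an estimated correlation (adjusted p = 0.0106).

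Genes of ribosomal proteins, the tricarboxylic acid (TCA) cycle and the NADH dehydrogenase were lower in ΔcceR. Of 45 genes of ribosomal proteins 40 fell and 1 rose, and the same numbers held when adjusted over the list alone. The largest decreases were in rpsP at -1.27 ± 0.05, rpmE at -0.99 ± 0.07, rpsU at -0.93 ± 0.09 and rpmB at -0.92 ± 0.10, with rpsN at -0.91 and rplL at -0.87. The gene tsf, which encodes a translation elongation factor, was lower by 1.02 ± 0.09 (limma, adjusted p = 3.69e-06). In the TCA cycle list 6 of 8 genes fell, led by mdh (malate dehydrogenase) at -1.10 ± 0.09, fumC (fumarase) at -0.81 ± 0.07, sdhA (succinate dehydrogenase) at -0.79 ± 0.08 and sucC (succinyl-CoA synthetase) at -0.68 ± 0.10. All 9 measured nuo genes of the NADH dehydrogenase fell, nuoL by 0.73 ± 0.14 and nuoH by 0.53 ± 0.09, with nuoK at -0.49 and nuoN at -0.45. In both of these lists the counts were the same when adjusted over the list alone. The ribosomal, TCA and NADH dehydrogenase lists were called down (camera, adjusted p = 2.73e-07, 0.0418 and 0.0307), with adjusted p = 0.360, 0.467 and 0.548 with an estimated correlation. The TCA call was lost without WT array 1 (adjusted p = 0.0602) and without ΔcceR array 2 (adjusted p = 0.0521).

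The remaining lists gave mixed or small changes in ΔcceR and were not called. The F-type ATP synthase was measured through 2 sets of genes of the same names, and the brighter atpA fell by 0.75 ± 0.08 while the dimmer atpA rose by 0.34 ± 0.06. The atpD pair gave -0.37 ± 0.11 and 0.29 ± 0.06, and the former lost its call without WT array 2 or 3 (adjusted p = 0.0574 and 0.0628) or ΔcceR array 1 or 3 (adjusted p = 0.0520 and 0.0690), and after quantile normalization (-0.25, adjusted p = 0.0585). Among cytochromes, cycA, which encodes cytochrome c2, rose by 0.45 ± 0.05 (0.68 after quantile normalization) and ccoO of the cbb3 oxidase fell by 0.27 ± 0.07, with 2 of 4 members not past the threshold. The chaperone genes dnaK and the brighter groEL fell by 0.50 ± 0.06 and 0.70 ± 0.08, whereas 6 of 10 heat shock genes did not pass the test. The storage genes glgC and phaC fell by 0.41 ± 0.05 and 0.30 ± 0.07, with 2 of 4 members not past the threshold. Of 22 flagellar and chemotaxis genes 20 did not pass the test, as did 13 of 16 nitrogen genes, 4 of 5 hydrogenase genes and 3 of 4 sugar uptake genes. The exceptions included flgC at 0.35, ureG at 0.29, hypB at 0.32 and xylF at 0.33, each higher in ΔcceR. Also past the threshold were fliK (-0.16), ureE (0.23), nifD (-0.14), clpA (0.25) and the dimmer groEL (0.16), but each lost its call when at least 1 of the WT or ΔcceR arrays was left out, with adjusted p of 0.0537 to 0.104. The hydrogenase list held only hyp genes, and the sugar uptake list held xylF, ugpA, ugpB and ugpE. Some members of these lists were dim in WT, such as fliK (7.56), nifD (7.52) and ugpA (7.24). Array medians were 8.01 to 8.06, so changes of such dim members may be understated. Others, such as xylF (10.43), were brighter. The list of the Calvin cycle had 2 measured genes, too few for a list test, of which cbbX was higher by 0.30 ± 0.07. Adjusted over the list alone, 2 cytochrome genes were lower, 1 flagellar gene was higher and 0 lower, and the other counts of these lists were the same. The glycolysis list had a median of -0.28 and a mean of 0.17. The ATP synthase and cytochrome lists had medians of -0.04 and -0.13, close to the -0.12 of all named genes.

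Over all probe sets, 1709 of 4490 differed between ΔcceR and WT, 709 higher and 1000 lower (limma with Benjamini-Hochberg adjustment, threshold of 0.05). Among the 514 named genes 65 were higher and 214 lower. At an absolute log2 fold change of at least 1 the number was 91, with 52 higher and 39 lower.

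**Figure D1:**
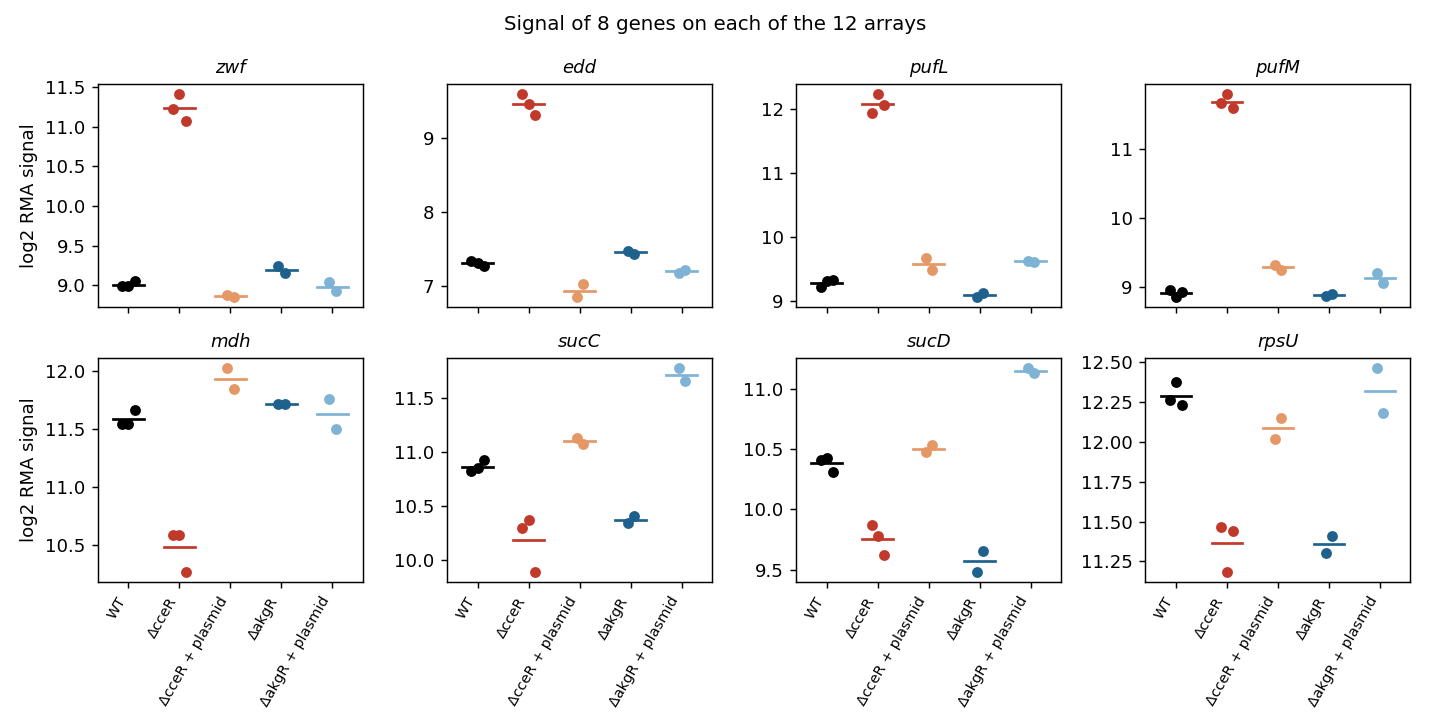
Log2 RMA signal of 8 genes on the 12 arrays, with a point per array and a bar at the mean of each strain; each panel has its own vertical scale. The ΔcceR arrays stand above WT for zwf, edd, pufL and pufM and below it for mdh, sucC, sucD and rpsU, and sucC and sucD are highest in ΔakgR with its plasmid.

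In ΔcceR with cceR returned on the plasmid the same groups moved the other way. No strain with an empty plasmid was among the samples. Effects of carrying or inducing the plasmid can therefore not be told apart from return of the gene, here and for akgR. Relative to ΔcceR, the Entner-Doudoroff genes edd, zwf, pgl and the responding eda changed by -2.52 ± 0.08, -2.37 ± 0.08, -2.10 ± 0.09 and -1.24 ± 0.11 (SE, n = 2 and 3 arrays), so that 4 of 5 members were lower and 1 did not pass the test, also when adjusted over the list alone (camera, adjusted p = 7.97e-06), with adjusted p = 0.132 with an estimated correlation. The isomerase gene pgi fell by 1.22 ± 0.06. Of the photosynthetic genes 16 of 27 fell and 0 rose, 17 when adjusted over the list alone, with pufL at -2.49 ± 0.08, pufM at -2.41 ± 0.07, pufX at -2.17 ± 0.11 and puhA at -1.99 ± 0.06. That list was called down (camera, adjusted p = 3.44e-14), also with an estimated correlation (adjusted p = 0.0130). Of the 5 pufA probe sets, numbers 2 and 4 (-2.34 and -2.72) were lowered further than the other 3 (-1.78 to -1.94) by 1 of the plasmid arrays, on which these positions were low in other genes too.

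In the same comparison 40 of 45 ribosomal protein genes rose and 0 fell, with rpsP at 1.45 ± 0.05, rpsN at 1.12 ± 0.09, rpmE at 1.07 ± 0.08 and rplQ at 0.94 ± 0.10. Adjusted over the list alone, 43 rose and 1 fell. The elongation factor gene tsf rose by 1.20 ± 0.10. Of the TCA genes 6 of 8 rose, with mdh at 1.46 ± 0.10, sdhA at 0.98 ± 0.09, fumC at 0.97 ± 0.08 and sucC at 0.91 ± 0.11. All 9 measured nuo genes rose, nuoL by 0.94 ± 0.15 and nuoK by 0.73 ± 0.10, with nuoH at 0.70 and nuoI at 0.61. The 3 lists were called up (camera, adjusted p = 2.72e-09, 0.0223 and 0.0121), with adjusted p = 0.322, 0.462 and 0.528 with an estimated correlation, and the TCA and NADH dehydrogenase counts were the same when adjusted over the list alone. The gene exbD, part of the system that energises outer membrane transport, rose by 0.95 ± 0.07. The brighter groEL and dnaK rose by 0.85 ± 0.09 and 0.61 ± 0.07, and the brighter atpA rose by 0.93 ± 0.08 while the dimmer fell by 0.60 ± 0.07, and the atpD pair was at 0.59 and -0.31. In the other lists, which were not called, glgC rose by 0.47 ± 0.06, cycA fell by 0.48 ± 0.06, ccoO rose by 0.44 ± 0.08 and ureG was at -0.28, while 21 of 22 flagellar, 13 of 16 nitrogen, 4 of 5 hydrogenase and 3 of 4 sugar uptake genes did not pass the test. Other members past the threshold were eno (0.46), ccoP (0.37), phaC (0.29), fliK (0.22), nifD (0.17), hypB (-0.35), cbbX (-0.27), xylF (-0.25), clpA (-0.25), ureE (-0.24) and the dimmer groEL (-0.18), each of which lost its call when at least 1 of the arrays was left out, with adjusted p of 0.0535 to 0.155, and fliK was at 0.15 without plasmid array 2. Adjusted over the list alone, 0 flagellar genes passed the test and 3 heat shock genes were higher and 3 lower, against 2 and 2. The glycolysis list had a median of 0.31 and a mean of -0.15, since gpmI rose by 0.31 while pgi fell.

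In total 1587 probe sets differed between ΔcceR with its plasmid and ΔcceR, 954 higher and 633 lower. Of the 1709 probe sets called in ΔcceR against WT, 1311 (76.7%) were called in the opposite direction on return of the gene and 0 in the same direction. Both comparisons use the ΔcceR arrays, which by itself pulls the fold changes apart. Independent lists of these sizes, which leave the sharing out of account, would share 100 and 212 in the respective directions, against 512 and 799 observed. The fold changes correlated at -0.91 across probe sets, against -0.44 in 100 simulations of unchanged strains with the same sharing, with a covariance of -0.117 against -0.00277. With the ΔcceR arrays divided so that the comparisons had none in common, in 6 ways, 751 to 1000 were reversed, 3.83 to 4.73 times the number for independent lists. Among named genes 251 were reversed, and those with the largest changes in both comparisons were pufL, pufM, zwf, pufX, edd and pgl.

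**Figure D2:**
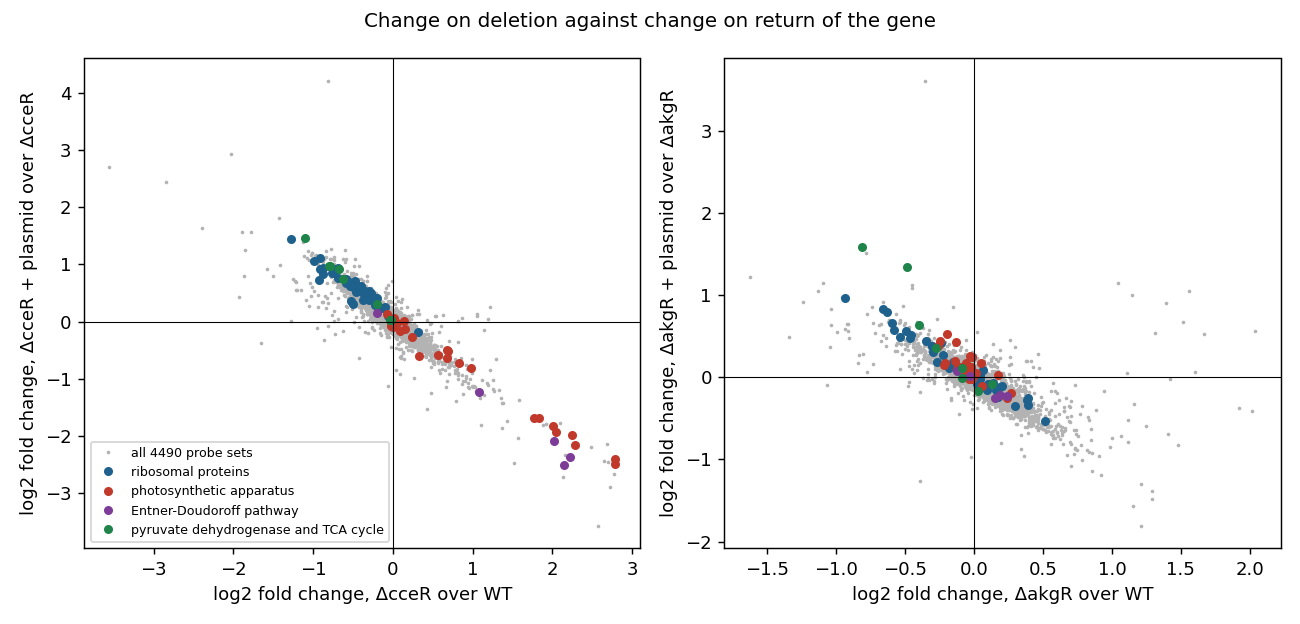
Log2 fold change of each probe set on deletion (horizontal) against its change on return of the gene by the plasmid (vertical), for cceR on the left and akgR on the right, with the members of 4 gene lists coloured. Both axes share the arrays of the deletion strain; 1311 of 1709 called probe sets were reversed for cceR and 549 of 836 for akgR.

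The second deletion asked which transcripts depend on AkgR. In ΔakgR the succinyl-CoA synthetase genes sucD and sucC were lower than in WT by 0.81 ± 0.08 and 0.49 ± 0.11 on the log2 scale (SE, n = 2 and 3 arrays), as were sdhA by 0.40 ± 0.09 and fumC by 0.28 ± 0.08. In all, 4 of 8 TCA genes fell and 0 rose, also when adjusted over the list alone. Ribosomal protein genes moved both ways, with 14 of 45 lower and 5 higher, or 15 and 6 when adjusted over the list alone. The lower ones were led by rpsU at -0.93 ± 0.10, rplR at -0.66 ± 0.12, rplF at -0.63 ± 0.09 and rpsH at -0.59 ± 0.08, and also included rpsB at -0.58. The brighter groEL fell by 0.53 ± 0.09, and Pnp, which encodes the RNA-degrading polynucleotide phosphorylase, fell by 0.54 ± 0.09. Higher in ΔakgR were ctrA, a cell cycle regulator in related bacteria, at 0.79 ± 0.12, pgsA, an enzyme of phospholipid synthesis, at 0.70 ± 0.08, and rpoZ, the omega subunit of RNA polymerase, at 0.57 ± 0.06. The plasmid replication genes repC and repA rose by 0.66 ± 0.07 and 0.56 ± 0.09, pncA by 0.56 ± 0.06, ihfB, a subunit of the DNA-bending protein IHF, by 0.56 ± 0.13 and gcvH of the glycine cleavage system by 0.55 ± 0.09. Also lower was rplS at -0.54 ± 0.12, which was -0.32 without ΔakgR array 1.

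None of the 14 lists tested was called in ΔakgR against WT by camera, where 2 had an unadjusted p under 0.05 and the lowest adjusted p was 0.244, for the TCA list, nor with an estimated correlation (adjusted p of at least 0.812). Of the Entner-Doudoroff genes 0 of 5 passed the test, with pgl at 0.24 ± 0.09 and zwf at 0.19 ± 0.08. Of the photosynthetic genes 25 of 27 did not pass it. Single members past the threshold elsewhere included gltB of glutamate synthase at -0.27 ± 0.06, nuoC at 0.27 ± 0.06 and cycA at 0.30 ± 0.06. Others were cbbX (0.30), ccoO (0.26), ureG (0.25), tspO (0.24), clpB (0.19), atpA (-0.33) and hemT (-0.21), each of which lost its call when at least 1 of the arrays was left out, with adjusted p of 0.05 to 0.25. The call of atpA was also lost after quantile normalization (-0.22, adjusted p = 0.0893) and that of hemT after median centring (0.0551). Adjusted over the list alone, 3 nuo genes were higher and 2 lower, and 1 photosynthetic gene was higher and 0 lower. No member of the lists for glycolysis, flagella, sugar uptake, storage or hydrogenase passed it, and adjusted over the list alone 1 glycolysis gene was lower, where the largest changes included fliR at -0.19, fliN at -0.18, gpmI at -0.17, eno at -0.12, xylF at 0.16, ugpB at 0.10, hypD at -0.14, hypB at 0.14, glgA at 0.05 and glgX at -0.04. Of these, gpmI passed it after quantile normalization (adjusted p = 0.0331) and fliR without ΔakgR array 1 (0.0426).

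In total 836 probe sets differed between ΔakgR and WT, 466 higher and 370 lower, or 55.7% higher. This share depended on the processing, with 67.1% of 818 higher after median centring of each array, 50.1% of 1213 in a fit of these arrays alone and 46.2% of 1555 with array weights. Many of the 836 calls were lost without either ΔakgR array, which leaves 1 array of the strain. The size of a change could stay close. Without ΔakgR array 1 or 2 sucC was at -0.46 and -0.52, against -0.49 with both. The gene ihfB was at 0.54 and 0.58, against 0.56, whereas rplS moved from -0.54 to -0.32 without array 1. Without array 1 the calls of sucC (adjusted p = 0.0783), sdhA (0.0915), fumC (0.188), cycA (0.0609), gltB (0.0890), ihfB (0.0817) and rplS (0.0947) were lost, and without array 2 those of sucC (0.0553), fumC (0.0600), nuoC (0.146) and ihfB (0.0750); fumC was also lost without WT array 3 (0.0748).

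With akgR returned on the plasmid, sucD was higher than in ΔakgR by 1.58 ± 0.08 and sucC by 1.33 ± 0.12 (SE, n = 2 and 2 arrays), a fold of 2.99 and 2.52, and sdhA by 0.64 ± 0.10. The TCA list had 4 of 8 members higher and 0 lower, also when adjusted over the list alone, with fumC at 0.36 ± 0.08. The call of fumC was lost without ΔakgR array 1 (adjusted p = 0.10) and without plasmid array 1 (adjusted p = 0.0965). Among ribosomal proteins 14 of 45 rose and 4 fell (15 and 5 when adjusted over the list alone), with rpsU at 0.97 ± 0.11, rplR at 0.83 ± 0.13, rplF at 0.79 ± 0.09 and rpsH at 0.66 ± 0.08, and the brighter groEL rose by 0.70 ± 0.10. The genes that had been higher in ΔakgR were lower, with pgsA at -1.09 ± 0.09, ctrA at -1.0 ± 0.13, repA at -0.71 ± 0.10, rpoZ at -0.70 ± 0.06, ihfB at -0.68 ± 0.14, repC at -0.61 ± 0.08 and pncA at -0.59 ± 0.06. The gene cobS of cobalamin synthesis was lower by 0.61 ± 0.07. Of 27 photosynthetic genes 6 rose and 1 fell, also when adjusted over the list alone, with pufL at 0.53 ± 0.09. The call of ihfB was lost without ΔakgR array 1 (adjusted p = 0.0502) and without plasmid array 2 (-0.46, adjusted p = 0.0792).

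By camera 4 lists were called up on return of akgR, for the TCA cycle (adjusted p = 0.0210), the photosynthetic apparatus (0.0261), ribosomal proteins (0.0393) and flagella (0.0393). With an estimated correlation these were lost (adjusted p = 0.463, 0.463, 0.854 and 0.834), and after quantile normalization only the TCA list was called, with adjusted p = 0.122, 0.286 and 0.286 for the other 3. The flagellar call was also lost without the dimmest 25% of probe sets (0.0624) and the ribosomal call against all probe sets (0.0521). Without ΔakgR array 1 the ribosomal call was lost (adjusted p = 0.104), without ΔakgR array 2 the flagellar call (0.175), without plasmid array 1 the ribosomal call (0.146), and without plasmid array 2 the photosynthetic and flagellar calls (0.126 and 0.689). In the flagellar list 1 of 22 members passed the test on its own, and 0 did when adjusted over the list alone. The cytochrome list, with ccoO and cycA lower (-0.37 and -0.30), had adjusted p = 0.0548 and was called down without ΔakgR array 1 (0.0496). Single members past the threshold were crtA (0.44), pufA (0.43), pufX (0.38), fliN (0.28), nifD (0.21), cbbX (-0.37), nuoC (-0.37), ureG (-0.26) and clpB (-0.23), and these, ccoO and cycA each lost the call when at least 1 of the arrays was left out (adjusted p of 0.0550 to 0.234), with clpB at -0.14 without plasmid array 2. The call of pufX was also lost after median centring (adjusted p = 0.0596). The pufA value is that of its brightest probe set. Its 5 probe sets changed by 0.11 to 0.46, and 3 of them were called higher. On plasmid array 2 its probe sets 2 and 4 had a gap of -0.21 to the rest. No Entner-Doudoroff gene passed the test, with pgl at -0.23 and edd at -0.26, although edd did after quantile normalization (adjusted p = 0.0133) or median centring (0.0342). The ATP synthase, glycolysis, storage, sugar uptake and hydrogenase genes did not pass it either, where the largest changes included atpD at 0.29, atpA at 0.26, hypE at 0.20, hypB at -0.14, phaC at -0.08, glgC at 0.06, ugpE at 0.08, ugpA at -0.04, gpmI at 0.07 and eno at 0.06. In total 739 probe sets differed, 455 of them lower, and the count was 394 without ΔakgR array 1, 303 without ΔakgR array 2 and 336 without plasmid array 2.

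Of the 836 probe sets called in ΔakgR against WT, 549 (65.7%) were called in the opposite direction on return of akgR and 9 in the same direction. Independent lists would share 47.2 and 23.4 in the respective directions, against 351 and 198 observed, without regard to the shared ΔakgR arrays. With 1 ΔakgR array for each comparison 207 and 220 were reversed, against 17.7 and 16.9 for independent lists. The fold changes correlated at -0.75 across probe sets, against -0.55 in the simulations, with a covariance of -0.0415 against -0.00423. Among named genes 73 were reversed, led by rpsU, sucD, ctrA, pgsA, rplR and rplF. The count of 549 reversed probe sets fell most without either ΔakgR array or without plasmid array 2, each of which leaves 1 array in a strain.

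**Figure D3:**
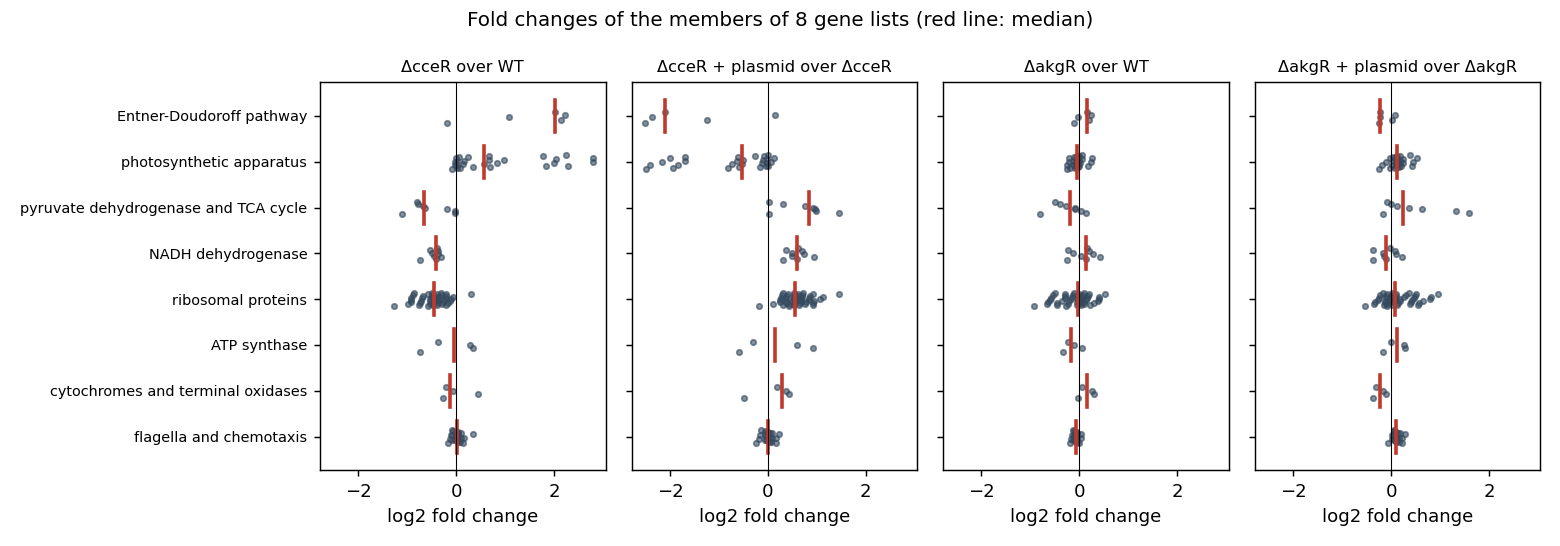
Log2 fold changes of the members of 8 gene lists, a point per gene with a red bar at the median, in the 4 comparisons of a deletion strain with WT and of a plasmid strain with its deletion strain. The Entner-Doudoroff median is 2.03 in ΔcceR over WT and -2.10 on return of cceR, whereas the ribosomal protein median goes from -0.46 to 0.56.

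The plasmid strains were close to WT. Between ΔcceR with its plasmid and WT 48 probe sets differed, 43 higher and 5 lower, and of the 1709 probe sets called in ΔcceR 21 were also called here in the same direction and 16 in the opposite one. Of the named genes pufM was higher by 0.37 ± 0.07 and edd lower by 0.37 ± 0.08. The count was 31 without WT array 2, 21 without plasmid array 2, and 30 when only the arrays of these 2 strains were fitted. Between ΔakgR with its plasmid and WT 68 probe sets differed, 60 higher and 8 lower, and of the 836 called in ΔakgR 46 were also called here in the same direction and 10 in the opposite one. Here sucC and sucD were above WT by 0.85 ± 0.11 and 0.77 ± 0.08, and pgsA was lower by 0.38 ± 0.08. The count was 36 without plasmid array 1 and 43 without plasmid array 2.

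The deletions were also set against each other, which gave 1803 different probe sets, 813 higher and 990 lower in ΔcceR. The largest differences among named genes were in pufL (2.98 ± 0.08), pufM (2.81 ± 0.07) and pufX (2.54 ± 0.11), higher in ΔcceR, and in mdh (-1.24 ± 0.10), nuoL (-1.16 ± 0.15) and rpmB (-1.10 ± 0.11), lower there. The count was 1165 without ΔakgR array 1 and 1076 without ΔakgR array 2. In the same direction in both deletions against WT were 351 probe sets, 176 higher and 175 lower, against 73.6 and 82.4 for independent lists. With the WT arrays divided so that the deletions had none in common, in 6 ways, 131 to 198 were shared, against 38.2 to 65.9 for independent lists. This division does not remove an offset common to all WT arrays. The fold changes of the deletions correlated at 0.29 across probe sets, and their covariance was 0.0237 against 0.00285 in the simulations. The simulated strains had no effects, so their correlation of 0.45 comes from the shared WT arrays alone. It is therefore no reference for the 0.29. In the 6 divisions of the WT arrays the fold changes correlated at 0.14 to 0.29. Without ΔakgR array 1 or 2 the shared count was 204 and 183. Among named genes 54 were shared, and rpsU (-0.93 in both), ctrA (1.43 and 0.79 in ΔcceR and ΔakgR), sucD (-0.63 and -0.81), rpsB (-0.59 and -0.58), Pnp (-0.65 and -0.54) and the brighter groEL (-0.70 and -0.53) had the largest changes common to both. Of these, only ctrA differed between the deletions in the direct test (0.64, adjusted p = 0.00121).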

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

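The 2 deletions against WT called 127 probe sets in opposite directions, with 16 named genes among them, against 351 in the same direction. ΔcceR had 709 higher and 1000 lower calls among 4490 probe sets, and ΔakgR 466 and 370. Independent lists of these sizes would share more opposite calls than 127, so the 127 are no excess. Such lists leave the shared WT arrays out of account. The differences of the 127 probe sets between ΔcceR and ΔakgR follow almost directly from the opposite calls against the same WT arrays, so the direct test adds no support of its own. The gene pncA, a nicotinamidase, was lower in ΔcceR by 0.45 and higher in ΔakgR by 0.56, a difference of -1.01. The gene fnrL, an oxygen-responsive regulator, differed by 0.90 (0.42 in ΔcceR and -0.48 in ΔakgR) at its brightest probe set, and of its 5 probe sets 4 were called higher in ΔcceR and 2 lower in ΔakgR. The 3 ribosomal protein genes that follow were lower in ΔcceR and higher in ΔakgR, rplX with a difference of -0.98, rpmF with -0.87 and rpmI with -0.76. The ribosomal protein gene rpmD went the other way, with a difference of 0.61, and was the only ribosomal protein gene of 45 called higher in ΔcceR. No explanation was tested for these differences, and the ΔakgR side rests on 2 arrays.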

How the results depend on the processing

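The settings without the 80 probe sets of the highest numbers, with all probe sets as background and with no array in common were chosen after seeing the data. No called list or called named gene turned its direction under the alternatives run for it. Array weights turned the share of higher calls in ΔakgR against WT from 55.7% to 46.2%, and with all probe sets as background the cytochrome and heat shock lists, not called, changed sides for ΔcceR against WT and return of cceR. Quantile normalization, median centring, robust eBayes, an intensity trend, the filter on dim probe sets and the table without those 80 probe sets kept every count of differing probe sets within 1.5 times. Array weights raised ΔakgR against WT from 836 to 1555, and the fit of the compared arrays alone lowered ΔcceR with plasmid against WT from 48 to 30. The typical within-strain SD was 0.042 in ΔakgR, 0.053 in WT and 0.078 in ΔcceR. It was 0.064 in ΔcceR with its plasmid and 0.056 in ΔakgR with its plasmid. The main fit uses 1 spread per probe set for all strains. The cause of these shifts in the counts was not tested. An absolute log2 fold change of at least 1, which by construction keeps fewer, left 91 (ΔcceR against WT), 33 (ΔakgR against WT), 105 (return of cceR), 21 (return of akgR), 5 and 15 (plasmid strains of cceR and akgR against WT) and 87 (ΔcceR against ΔakgR). An adjusted p under 0.01 gave 1131, 431, 329, 20, 42 and 1123 for ΔcceR and ΔakgR against WT, return of akgR, the plasmid strains of cceR and akgR against WT and ΔcceR against ΔakgR. Replicate numbers did not pair the arrays: same-numbered arrays of ΔcceR and WT had correlated deviations of -0.22 to 0.01, and 0 of 3 correlated best with their own number. For ΔakgR against WT and ΔcceR against ΔakgR 1 of 2 did, at correlations of at most 0.07, and in the remaining comparisons 0 did. The replicate block gave 1644 and 727 probe sets for ΔcceR and ΔakgR against WT and 1404 for return of cceR. It moved ΔcceR with plasmid against WT from 48 to 29. Of the named genes and lists 8 lost and 1 gained a call. The lost calls included fumC in ΔakgR against WT (limma, adjusted p = 0.0574). The gained call was that of the cytochrome list, down on return of akgR (camera, adjusted p = 0.0445). Estimated correlations left 1 of 5 list calls for ΔcceR against WT, 1 of 5 for return of cceR and 0 of 4 for return of akgR, and quantile normalization left 1 of the 4. Without each array in turn, where the lone array of a strain is assumed to vary like the others, the counts ranged from 1311 to 1647 (ΔcceR against WT), 361 to 650 (ΔakgR against WT), 1193 to 1574 (return of cceR), 303 to 514 (return of akgR), 21 to 57 and 36 to 60 (plasmid strains of cceR and akgR against WT) and 1076 to 1795 (ΔcceR against ΔakgR). Reversed calls ranged from 1052 to 1310 for cceR and 223 to 453 for akgR, shared calls from 183 to 383, and called lists from 4 to 5, 0 to 0, 5 to 5 and 2 to 4. With no array in common between the comparisons, reversed calls were 751 to 1000 for cceR and 207 to 220 for akgR, and shared calls 131 to 198. Fewer arrays explain part of the loss by construction. Of the values for single named genes and lists, 1057 stayed on their side of the threshold without 1 array, 118 lost and 2 gained a call. The arrays, at 2 or 3 per strain, limit all of these counts.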

Other observations

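Genes were grouped by the first 3 letters of their symbols after seeing the data, in families of at least 5 outside the lists. In ΔcceR 4 of 5 sec genes of protein export were lower than in WT (median -0.47), as were 6 of 10 pur genes of purine synthesis (-0.34), 5 of 6 dap genes of lysine synthesis (-0.28), 5 of 8 fab genes of fatty acid synthesis (-0.26) and 7 of 10 cob genes of cobalamin synthesis (-0.22), with 1 cob gene higher. None of the 14 families stood apart from the other named genes, whose median was -0.12 (camera, lowest adjusted p = 0.650, and 0.784 with an estimated correlation). The hut genes of histidine use had 0 of 5 past the threshold. Outside these families, fusA, which encodes an elongation factor, was higher in ΔcceR by 1.04 while most ribosomal protein genes fell, and was chosen after its value was seen. The oxygen- and light-responsive regulator gene appA was higher by 1.10 to 1.37 at its 5 probe sets.

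The tests of the WT arrays and of the genes with 5 probe sets were chosen only after the result was seen, whereas the others were written down before they were run. The 1709 probe sets that differed between ΔcceR and WT are not a property of the WT arrays alone, since 1.23% of them were also called in the same direction between ΔcceR with its plasmid and WT. The 10 splits of the 6 arrays are too few to give a share under 0.05, and the real split called 1709 and the highest other split 0. Every other split mixes arrays of both strains, which puts the strain difference into the spread, so its low count is no support. Against ΔcceR all 4 other strains were higher in 492 probe sets and lower in 322. The labels name no batch, and none was tested. The WT samples have a protocol text of their own, and an offset common to the WT arrays would enter every comparison with WT. The loss of CceR stays open as the biological explanation.

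The ribosomal protein genes were bright, with a median of 12.2 on the log2 scale against 8.04 over all probe sets, and the ΔcceR arrays had a narrower spread of values than WT. A compression of bright signals on those arrays could lower them all. Each gene was compared with the 50 other probe sets nearest to it in level, which had themselves a median change of -0.20. The ribosomal protein genes lay a further -0.25 below these (median, quartiles -0.52 and -0.12), with 39 of 45 below, so compression does not account for the whole decrease, although part of the median of -0.46 is shared with bright probe sets of other kinds. No such comparison was made for the TCA and NADH dehydrogenase lists, of which mdh and nuoI, for example, were also bright in WT (11.6 and 11.7). Part of their decrease may likewise be shared with other bright probe sets. For the ribosomal protein genes the deletion, and slower growth of the strain, stay open and were not tested.

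A total of 5 genes had 5 probe sets each, and on array 2 of ΔcceR with its plasmid numbers 2 and 4 of each were low. After the median of each probe set over all arrays was subtracted, their gap to the other 3 had a median of -0.91 over fnrL, appA, ppsR, bchF and pufA. A change in the level of whole transcripts would not give this gap, since it would move all probe sets of a gene. Changes confined to part of a transcript were not tested. A fault of that array alone could be the source, but array 2 of ΔakgR with its plasmid had a median gap of -0.21, with all 5 genes below 0. Array 1 of ΔcceR with its plasmid had -0.10, also with all 5 below 0, whereas array 1 of ΔakgR with its plasmid had 0.06 with 1 below 0. The source stays open, and no biological explanation was tested.

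Neighbouring probe set numbers changed together in ΔcceR, with a correlation of 0.54 between neighbours against at most 0.05 in 1000 shuffles. A candidate explanation is that numbers follow gene order, so that neighbours share an operon, and in the longer stretch, 203 of 403 named genes of chromosome 1, numbers and RefSeq positions had a Spearman's rho of 0.96. Operons themselves were not tested.

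The unnamed probe set 2581 stood at 12.01 ± 0.07 (SD, n = 2) in ΔcceR with its plasmid, 8.60 ± 0.03 (n = 3) in WT and 7.79 ± 0.01 (n = 3) in ΔcceR. It stood at 8.59 in ΔakgR and 8.54 in ΔakgR with its plasmid. The unnamed probe set 1880 stood at 10.73 ± 0.19 (SD, n = 2) in ΔakgR with its plasmid, 7.48 ± 0.04 (n = 3) in WT and 7.12 ± 0.04 (n = 2) in ΔakgR. Its level was 7.61 in ΔcceR and 7.50 in ΔcceR with its plasmid. These 2 probe sets were chosen after their values were seen, and the annotation does not say which genes they measure. All 4 other strains were higher than WT in 13 unnamed probe sets, of which 8 lay within 20 consecutive numbers. The 80 probe sets of the highest numbers, all unnamed, had a median within-strain SD of 0.29 on the log2 scale against 0.08 for the rest, and 51 of them were called in ΔcceR against WT.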
